A study of Daphnia magna with 20 samples.

How the data were processed

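RNA from pools of whole Daphnia magna was sequenced in 20 libraries, 5 in each of 4 groups (vehicle control, ethylene acrylic acid copolymer at 2.3e11 and at 2.3e12 particles per litre, and fumed silica at 2.3e12), after a 21-day exposure. The labels describe poly-A selection, a stranded library kit and the pooling of several libraries for sequencing. Which libraries shared a pool, and how many daphnids or separate cultures went into each sample, is not given in the sources used here, so sequencing pools could not be examined and p-values measure the spread between these samples. The submitters' processing notes name Salmon 0.12.0 and R 3.4.3. The reference, its annotation and the step that joined transcripts into names are not given in the sources used here.

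The deposited table holds estimated counts (expected counts of the kind Salmon reports) for 7784 names in 20 columns, all of which could be matched to a library. The table is called normalized. Low values, however, lay within 0.01 of whole multiples of a constant of 0.979 to 1.01 per library in 18.0% to 27.2% of cases. A constant fixed beforehand would give 2% by chance. This constant was the best fit for each library within a narrow range, so its size was limited by the search and its chance share is higher. The library totals ran from 7912434 to 95906857 counts, a 12.1-fold range. The values were therefore treated as estimated counts not scaled to a common depth. Names are protein descriptions, 1431 of them with an added gene tag, and none matched the symbols of the reference table, so no genome positions, lengths or GC contents were available. Bias from positions and GC contents could not be checked, and bias from length only roughly, through proteins taken as short or long by name. Copies that share a description may have been summed or may share reads, so values of names from gene families, the ribosomal and cuticle proteins among them, are uncertain as to the gene. None of the 40 pairs of replicate libraries was identical.

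The design fixed before the data were examined named limma on log2 values for a normalised table and the edgeR quasi-likelihood test should the values turn out to be counts. Since they were estimated counts, edgeR took limma's place. Values were rounded, names with a value of at least 1 in at least 5 libraries were kept (7564 tested, 220 left out), and libraries were scaled by TMM (factors 0.898 to 1.14). A mean per group was fitted to all 20 libraries with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1 for list tests, DESeq2 1.42.0 as an alternative, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 for checks and figures). The 5 comparisons were the 3 exposures against control, nano_high against nano_low, and nano_high against silica. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and a name past it is said to be called. CPM are counts per 1000000 of the TMM-scaled total, and principal components used log2 CPM with a prior count of 2. Depth sets the precision: for a group whose libraries are all at 0 a floor of 3 counts over the group was used for folds, which covers counting error only.

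In all 27 gene lists were fixed beforehand as patterns on the names, and 26 had at least 5 tested members. These were hemoglobin, cuticle proteins, chitin turnover, peritrophic matrix and mucins, digestive proteases, digestive carbohydrases and lipases, antioxidant defence, cytochrome P450, phase II conjugation, ABC transporters, heat shock and chaperones, metal handling, innate immunity, ecdysteroid and juvenoid signalling, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, fatty acid and lipid metabolism, proteasome, DNA replication and cell cycle, histones, germline and oogenesis, muscle, eye and phototransduction, neural transmission, and collagen and extracellular matrix. The vitellogenin and yolk list had 4 members and was not tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list's names move on balance one way and compares it with no other names. With the estimated correlation 0 lists passed in any comparison (lowest adjusted p 0.125, 0.394, 0.587, 0.739 and 0.707 in the order of the comparisons above), and fry passed 2, 6, 2, 0 and 1. The sign of the median, the mean and the test of a list differed in 3, 2, 2, 6 and 3 of the 26 lists, none of them a list that passed. A list score per library is the mean of its members' centred log2 CPM.

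Named genes were chosen by a rule fixed beforehand. Per comparison it takes the 8 called names with the largest rise and the 8 with the largest fall that have an informative description, the 2 largest in each direction whatever the description, and up to 4 members with the smallest p of each list that passed camera or had at least 3 called members. Names beginning with conserved protein or expressed protein were treated as uninformative. Where a list that passed had no called member, the 1 with the smallest p is given with its values, and where a comparison had no called name, the 3 rising and 3 falling names with the smallest p are given. Not every name the rule takes is printed. Other names in the text (collagen alpha-1v chain, alpha-globin transcription factor cp2, names called in all 3 exposures and those under other observations) were chosen after their values were seen.

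Comparisons that share the controls were set beside 200 simulated draws of unchanged groups and 20 splits of the control libraries. Shared calls were set beside 200 such draws, with lists of the real sizes taken by limma's t. Their permutation p are one-sided, for as many names in common or more. The pipeline was tested on simulated data with 100 names changed 2-fold and 100 changed 1.5-fold: over the 5 comparisons it called 58% to 68% of the former and 7% to 16% of the latter, and 1 to 6 of 7304 unchanged names. The changed names were taken from those with an average log2 CPM above 1, and all names were drawn independently. In the real libraries names vary together, so these rates are not the error rates of the data. Alternatives fixed beforehand were other filters, median-ratio scaling, quantile normalization, sample weights, other variance models, other pseudocounts with limma, DESeq2, a fit of only the 2 groups compared, names whose groups do not overlap, the replicate number as a block, an estimated correlation, and each library left out in turn. Added after the data had been seen were thinning every library to the smallest total, the first principal component as a covariate, the 3 most abundant names left out, limma with a pseudocount of 1, list members cleaned of false matches, and the fit without silica 5 or without the 5 libraries with a first component below -30. The exact permutation tests of list scores, the draws for shared calls and the medians of short and long proteins were also added then.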

Results

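Whole water fleas (Daphnia magna) were compared after a chronic exposure of 21 days to particles of an ethylene acrylic acid copolymer or to fumed silica. The 20 RNA libraries, each made from pooled animals, fell into 4 groups of 5: vehicle control, polymer at 2.3e11 particles per litre (nano_low), polymer at 2.3e12 particles per litre (nano_high), and fumed silica at 2.3e12 (silica). The labels describe the stage as neonates less than a day old, while the protocol runs to day 21, so the age of the animals at RNA sampling is not settled by the sources used here. The table held estimated counts for 7784 names. Library totals ran from 11918440 to 26562258 counts in control, from 9689064 to 40227246 in nano_low, from 39087882 to 95906857 in nano_high and from 7912434 to 54862334 in silica. Each of the 5 nano_high libraries was therefore deeper than each of the 5 control libraries. A single name, copper-zinc cu-zn superoxide dismutase., took 4.37% to 19.26% of the counts of a library. Values below are CPM (counts scaled to a library total of 1000000) as mean ± SD with n = 5 libraries per group, and tests are edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 7564 names.

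**Figure D1:**
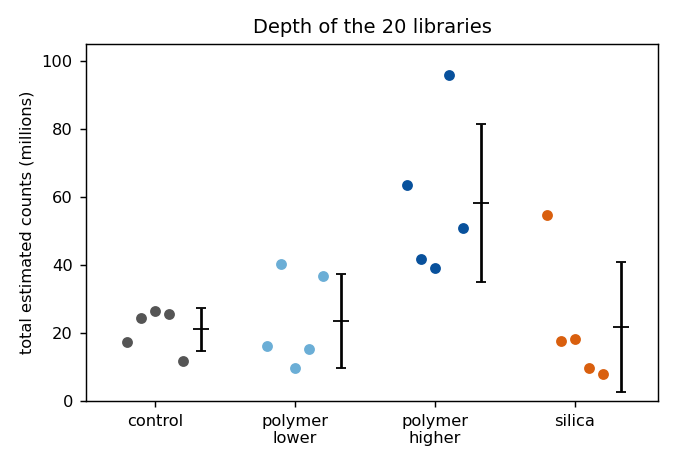
Total estimated counts (y axis, in units of 1000000 counts) of each of the 20 libraries by group; points are libraries and bars the mean ± SD of 5 libraries. The nano_high totals, 39.09 to 95.91, all lie above the control totals, 11.92 to 26.56.

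The widest spread among the libraries lay along cuticle and collagen transcripts, the proteins of the exoskeleton and of the matrix between cells. The first principal component of log2 CPM held 38.9% of the variance, of which 24.4% lay between the groups, and 19 cuticle proteins and 14 collagen and extracellular matrix names were among the 100 names with the strongest loadings at its positive end. Control 4 and 5, nano_low 1, and nano_high 4 and 5 lay at the negative end, at -54.0, -55.2, -55.1, -53.2 and -33.6, and no silica library did. One of these names, collagen alpha-1v chain, had 158 ± 182 CPM in control, with libraries from 0.570 to 374 CPM. Over the 20 libraries the first component also followed the scores of other lists. Its r was 0.951 with innate immunity, 0.949 with neural transmission and 0.915 with muscle. With the 4 yolk names, germline and oogenesis, and DNA replication and cell cycle it was -0.887, -0.861 and -0.838. Component 3 held 7.90% of the variance, of which 66.2% lay between the groups, and was drawn beside the first for that reason.

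**Figure D2:**
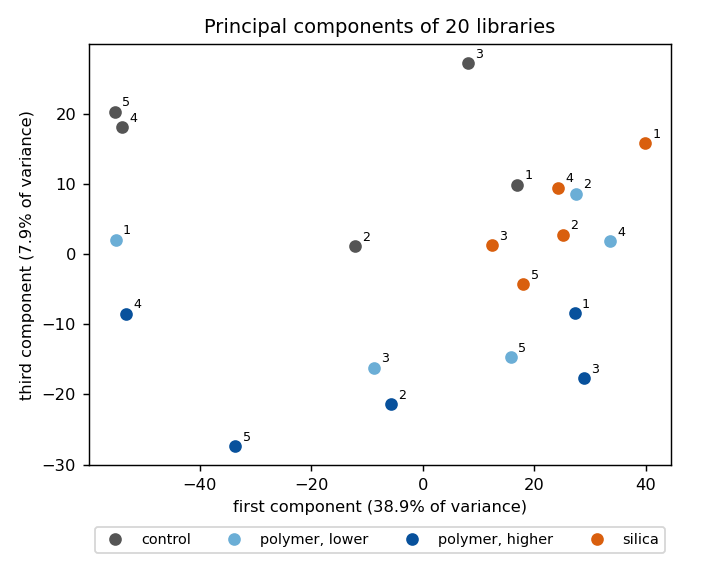
Principal components 1 and 3 of log2 CPM (scores, with the share of variance on each axis); each point is a library, numbered by replicate and coloured by group. Control 4 and 5, nano_low 1, and nano_high 4 and 5 lie at the left, from -55.2 to -33.6, apart from the other 15 libraries.

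Against control, names called lower at the lower polymer concentration included ribosomal proteins and metal handling names. As lists both passed by fry (adjusted p = 0.0155 and 0.00590). Neither passed by camera with an estimated correlation (0.326 and 0.125). Exact permutation tests of list scores gave an adjusted p of 0.206 each. The metal handling list had the smallest p that 5 against 5 libraries allow (0.00794). Even that p stood at 0.206 after adjustment over 26 lists, so these exact tests do not decide for either list. Of 97 cytosolic ribosomal proteins, the building blocks of the ribosome, 17 fell and 0 rose, and 57 fell adjusted over the list alone, with a list median log2 fold change of -0.39. Among them 60s ribosomal protein l23 fell from 489 ± 26.1 to 291 ± 31.1 CPM (log2 fold change -0.75, SE 0.11, edgeR adjusted p = 0.00616), and 40s ribosomal protein s27 fell from 530 ± 24.3 to 344 ± 45.8 CPM. 60s ribosomal protein l37a/arp2_g3347 and 40s ribosomal protein s16 fell by 0.86 and 0.59 on the log2 scale, and 1 other name for s16 was also called. The lowest adjusted p belonged to 30s ribosomal protein s8/arp2_g2243, a name outside that list, which fell from 98.5 ± 9.48 to 40.1 ± 10.6 CPM (log2 fold change -1.30, SE 0.16, edgeR adjusted p = 0.000937). Beside the ribosomal list, 44 names of short proteins in no list had a median of -0.15 (95% interval -0.30 to -0.0591), and 61 of long proteins 0.21 (0.10 to 0.25).

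Of 19 metal handling names, 2 fell in nano_low, and 7 fell and 1 rose adjusted over the list alone (list median -0.15). They were metallothionein protein crs5, named for a small metal-binding protein, at 89.4 ± 17.6 against 176 ± 58.8 CPM in control (log2 fold change -0.98, SE 0.20, edgeR adjusted p = 0.0314), and cation efflux protein/ zinc transporter/arp2_g4539 (log2 fold change -1.07). Ribonuclease h/arp2_g1421 fell by 1.06, wnt-2b, a secreted signalling protein, by 0.79, growth hormone-inducible soluble protein by 0.83 and adp-ribosylation factor protein 8b-a by 0.81 on the log2 scale. Conserved protein/arp2_g6938, 1 of 228 names that begin in this way, fell from 4.16 ± 0.849 to 1.21 ± 0.719 CPM. Of the 7 names that rose, methylcrotonoyl-coa carboxylase alpha chain, a subunit of a leucine breakdown enzyme, went from 3.90 ± 1.12 to 7.72 ± 1.14 CPM (log2 fold change 0.99, SE 0.22, edgeR adjusted p = 0.0447). The others were brother of odd with entrails limited/arp2_g9170, a zinc finger transcription factor in Drosophila (0.90), sodium/potassium-transporting atpase subunit alpha sodium pump subunit alpha na+/k+ atpase alpha subunit/arp2_g175 (0.69), cyclin dependent kinase 19 variant (0.61), surp and g-patch domain-containing protein (0.41), casc3 (0.40) and e3 ubiquitin-protein ligase mgrn1 (0.33).

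In total 47 names passed in nano_low against control, 7 higher and 40 lower, and 1065 had an unadjusted p under 0.05. By camera with the preset correlation of 0.01, 4 of the 26 lists passed: cytosolic ribosomal proteins (adjusted p = 9.89e-33), metal handling (9.91e-05), proteasome (5.17e-07; median -0.22) and collagen and extracellular matrix (0.0120; median 0.28). With an estimated correlation their adjusted p were 0.326, 0.125, 0.726 and 0.80. No member of the proteasome or collagen lists passed over all names, although 6 proteasome names fell adjusted over the list alone. The members with the smallest p were proteasome inhibitor pi31 subunit (17.9 ± 2.26 against 24.1 ± 3.06 CPM) and, in the collagen list, adam a disintegrin and metalloprotease (14.1 ± 0.904 against 18.7 ± 4.29 CPM), a membrane protease and not a matrix protein, whose value goes against the list's direction. With the first principal component as a covariate, the median of the collagen list was 0.01 (adjusted p = 0.884), and the list's adjusted p was 0.116, 0.0532 and 0.0998 without nano_low 2, control 4 and control 5. The number of names called was 236 without nano_low 1 and 9, 12, 12 and 13 without nano_low 2, 3, 4 and 5, and it was 23, 11, 8 and 10 without control 2, 3, 4 and 5. It was 3 when only the 2 groups entered the fit and 227 by DESeq2.

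The higher polymer concentration was set against control as the top exposure of the same material, and names called lower here included ribosomal, mitochondrial, antioxidant, metal handling and visual transcripts. Of 97 cytosolic ribosomal proteins 39 fell and 1 rose, and adjusted over the list alone 51 fell and 1 rose (median -0.38). 60s ribosomal protein l23 was at 288 ± 32.3 against 489 ± 26.1 CPM (log2 fold change -0.77, SE 0.11, edgeR adjusted p = 0.000879). 60s ribosomal protein l37a/arp2_g3347, 60s ribosomal protein l36a and 40s ribosomal protein s27 fell by 0.93, 0.73 and 0.68 on the log2 scale. 30s ribosomal protein s8/arp2_g2243 again had the lowest adjusted p, falling from 98.5 ± 9.48 to 29.7 ± 4.83 CPM (log2 fold change -1.73, SE 0.16, edgeR adjusted p = 1.27e-05). Of 84 oxidative phosphorylation names, the respiratory chain of mitochondria, 11 fell and 0 rose, and 15 fell adjusted over the list alone (median -0.23). As a list it did not pass by fry (adjusted p = 0.267), and the exact permutation test of its score gave an unadjusted p of 0.135. Nadh dehydrogenase [ubiquinone] 1 subunit c2 fell from 15.5 ± 3.03 to 6.82 ± 2.07 CPM, atp synthase subunit s protein from 903 ± 75.2 to 605 ± 70.3 CPM, and nadh dehydrogenase [ubiquinone] iron-sulfur protein 4, mitochondrial by 0.61 on the log2 scale. Nadh-ubiquinone oxidoreductase chain 4l fell from 177 ± 52.9 to 46.3 ± 17.8 CPM (log2 fold change -1.93, SE 0.34, edgeR adjusted p = 0.00266).

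Of 30 antioxidant defence names 10 fell in nano_high and 0 rose, and the count was again 10 adjusted over the list alone (median -0.28). Branchiostoma peroxiredoxin v protein/arp2_g2142, a peroxide-reducing enzyme, fell from 41.6 ± 6.04 to 21.2 ± 3.54 CPM, glutathione peroxidase from 175 ± 20.1 to 120 ± 20.3 CPM, and thioredoxin, mitochondrial from 73.7 ± 12.0 to 51.4 ± 2.62 CPM. Of 19 metal handling names 5 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (median -0.15). Metallothionein protein crs5 was at 75.2 ± 16.0 against 176 ± 58.8 CPM (log2 fold change -1.23, SE 0.20, edgeR adjusted p = 0.00194), and the iron storage proteins ferritin, heavy subunit and ferritin 2 light chain fell from 1932 ± 358 to 1091 ± 243 CPM and from 269 ± 53.6 to 166 ± 12.6 CPM. Of 31 eye and phototransduction names 7 fell, also adjusted over the list alone (median -0.07). These included phosrestin i arrestin b arrestin, which ends the light response of photoreceptors (149 ± 53.4 to 72.1 ± 17.1 CPM, with both names of this base called), and class a rhodopsin-like g-protein coupled receptor gprop1/arp2_g139, named for an opsin (64.0 ± 21.1 to 32.0 ± 6.91 CPM). Class a rhodopsin g-protein coupled receptor gpr5ht4 (log2 fold change -0.52) is in the list by its name, which points to a serotonin receptor. Of 26 proteasome names, the protein degradation complex, 6 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone (median -0.23), with proteasome subunit beta type-4, alpha type-6 and beta type-3 falling by 0.45, 0.39 and 0.39. Beside these lists, 44 names of short proteins in no list had a median of -0.26 (95% interval -0.41 to -0.11), and 61 of long proteins 0.36 (0.22 to 0.41).

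The names with the largest changes in nano_high included several of low abundance. Brother of odd with entrails limited/arp2_g9170 rose from 3.33 ± 0.706 to 8.80 ± 1.82 CPM (log2 fold change 1.40, SE 0.20, edgeR adjusted p = 0.000870), and methylcrotonoyl-coa carboxylase alpha chain from 3.90 ± 1.12 to 8.68 ± 2.09 CPM. Delta and notch epidermal growth factor-related receptor rose by 1.33, homeobox protein abdominal-a, a body segment regulator, by 1.34, mitogen-activated protein kinase kinase kinase 19 by 1.14, eukaryotic translation initiation factor/arp2_g3526 by 1.10 and glucosyl/glucuronosyl transferases/arp2_g27 by 1.40 on the log2 scale. Sterol regulatory element-binding protein/arp2_g3160 was at 0 in all 5 control libraries and at 2.03 ± 2.05 CPM in nano_high, at least 73.2-fold higher against a floor of 3 counts over the control group, or 40.3-fold without nano_high 1, where it was no longer called (adjusted p = 0.0560). Vacuolar protein sorting-associated protein vps13d/arp2_g6355 was at 0 in nano_high and at 2.58 ± 2.16 CPM in control. It was at least 241-fold lower against 3 counts over the group, or 161-fold without control 3. Conserved protein/arp2_g1399 was at 0 in nano_high and at 0.974 ± 0.927 CPM in control, with a lowest control library of 0. Its bound was 91.1-fold, or 67.5-fold without control 1. Vacuolar atpase assembly integral membrane protein vma21 fell from 6.03 ± 0.989 to 0.398 ± 0.360 CPM, and peptidyl-prolyl cis-trans isomerase fkbp14, a protein folding enzyme, from 8088 ± 5183 to 1702 ± 1106 CPM, with overlapping libraries. Potassium/chloride symporter/arp2_g622, ubiquinol-cytochrome c reductase iron-sulfur subunit/arp2_g2003 and cholinephosphate cytidylyl transferase b2/arp2_g1105 also fell, from levels of 0.254, 0.185 and 1.04 CPM in control. The first 2 were no longer called without control 4 and control 2 (adjusted p = 0.0981 and 0.163).

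Other lists held called members in nano_high without passing camera. By fry, ecdysteroid and juvenoid signalling and digestive carbohydrases and lipases did pass (adjusted p = 0.0493 each). Over all 7564 names 10.1% were called, and several of these lists lay below that share, so their counts alone do not mark a change of the list. Of 32 ecdysteroid and juvenoid signalling names, the hormones of moulting and reproduction, 3 rose and 2 fell: nuclear hormone receptor ftz-f1 beta (44.9 ± 5.67 to 68.4 ± 6.37 CPM), juvenile hormone resistance protein and nuclear receptor corepressor were higher, and juvenile hormone esterase binding protein 29, ld24657p was lower (log2 fold change -0.47). Of 68 digestive carbohydrases and lipases 4 fell and 1 rose, with hepatic triacylglycerol lipase falling from 207 ± 83.2 to 66.9 ± 18.3 CPM and alpha-amylase, a starch-digesting enzyme, from 3023 ± 868 to 1759 ± 376 CPM. Of 82 fatty acid and lipid metabolism names 4 fell and 2 rose, with acyl-coa-binding protein falling by 0.80, 3-hydroxyacyl-coa dehydrogenase type-2 by 0.61 and carnitine o-acetyltransferase by 0.33. Of 65 collagen and extracellular matrix names 4 rose and 0 fell, among them laminin subunit alpha-3 and laminin subunit beta-2, basement membrane proteins, at log2 fold changes of 0.61 and 0.55. The other 2 were fibronectin type iii domain-containing protein 3b (0.49) and disintegrin and metalloproteinase domain-containing protein (0.37), a membrane protease and not a matrix protein. Of 37 innate immunity names 4 fell and 1 rose; galectin-2 fell by 0.38 and class a scavenger receptor srcr domain with c-type lectin domain. rose by 0.58, while palmitoyl-protein thioesterase 1 precursor (-0.57) and ubiquitin thioesterase otub1 (-0.51) are enzymes whose names match the list by wording alone. Of 47 heat shock and chaperone names 3 fell and 1 rose, and the one that rose was heat shock 70 kda protein 4l (log2 fold change 0.24); those that fell were bag family molecular chaperone regulator, proteasome assembly chaperone and tubulin-specific chaperone cofactor e protein. Of 18 histone names 2 rose and 1 fell, with histone h1.0/sw at 0.66 and histone h2a type at -0.36.

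In total 761 names passed in nano_high against control, 391 higher and 370 lower, and 54 of them changed over 2-fold. The side with more calls turned under other settings (182 higher and 267 lower without control 3). By camera with the preset correlation 6 lists passed: cytosolic ribosomal proteins (adjusted p = 1.09e-16), oxidative phosphorylation (8.52e-06), antioxidant defence (8.88e-05), proteasome (0.000286), metal handling (0.00153) and eye and phototransduction (0.0273). With an estimated correlation their adjusted p were 0.511, 0.785, 0.511, 0.751, 0.394 and 0.511. By fry they were 0.0219, 0.267, 0.0144, 0.0723, 0.00332 and 0.0493, so oxidative phosphorylation and proteasome did not pass. For eye and phototransduction the adjusted p by the preset correlation was 0.0575 and 0.0675 without nano_high 5 and control 5. It was 0.0965 with names that match the list by wording alone taken out. The number of names called was 488 and 413 without nano_high 2 and 3, and 449 and 488 without control 3 and 4. It was 1152 by DESeq2 and 1748 with the first principal component as a covariate, and 372 when only the 2 groups entered the fit.

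Names called at the lower polymer concentration were also called at the higher one. All 7 names called higher and all 40 called lower in nano_low were also called in the same direction in nano_high. Brother of odd with entrails limited/arp2_g9170 and methylcrotonoyl-coa carboxylase alpha chain were among the shared rises, and metallothionein protein crs5 and 60s ribosomal protein l23 among the shared falls. Both comparisons used the same 5 controls, which makes such lists agree by itself. In 200 permutations of within-group deviations into groups with shared controls, lists of these sizes had in common 3.95 higher names (95% range 0 to 7, permutation p = 0.0846) and 17.7 lower names (1.98 to 35, highest 39, permutation p = 0.00498). Across 7564 names, which are not independent replicates, the log2 fold changes had r = 0.747 and a covariance of 0.0783, against a simulated mean r of 0.464 (95% range -0.312 to 0.869) and a simulated mean covariance of 0.0350 (-0.0192 to 0.115). Both values lie within their simulated ranges. With the controls split between the comparisons, the mean r over 20 splits was 0.353 (-0.172 to 0.679) and the mean covariance 0.0431.

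**Figure D3:**
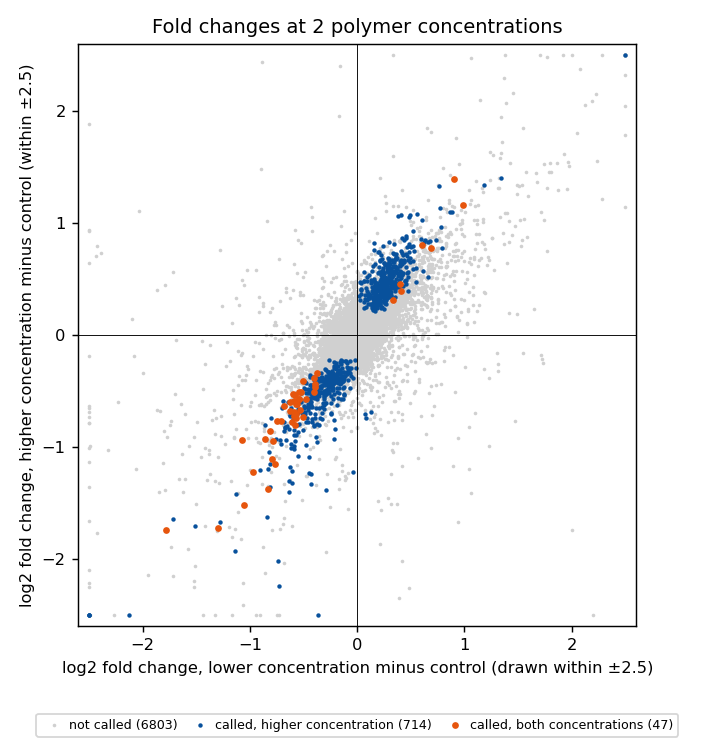
Log2 fold change of each of 7564 names against control at the lower (x axis) and higher (y axis) polymer concentration; points are names, coloured by whether they were called, and 60 names beyond ±2.5 are drawn at the edge. The 47 names called at both concentrations lie in the lower left (40) and upper right (7) of the plot.

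Fumed silica at 2.3e12 served as a particle of another material, and against control its clearest change was again in the ribosome. Of 97 cytosolic ribosomal proteins 25 fell and 0 rose, and adjusted over the list alone 69 fell and 1 rose (median -0.45). 60s ribosomal protein l23 was at 298 ± 44.0 against 489 ± 26.1 CPM (log2 fold change -0.71, SE 0.11, edgeR adjusted p = 0.0227), and 60s ribosomal protein l13a fell from 1456 ± 72.0 to 966 ± 113 CPM. 40s ribosomal protein s16/arp2_g6159 and 40s ribosomal protein s16 fell by 0.63 and 0.51, and 60s acidic ribosomal protein p2, 60s acidic ribosomal protein p1 and 40s ribosomal protein s20 by 0.81, 0.76 and 0.78 on the log2 scale. Of 26 proteasome names 1 fell, 26s proteasome non-atpase regulatory subunit/arp2_g1763 (log2 fold change -0.61), and 12 fell and 1 rose adjusted over the list alone (median -0.26). Beside these lists, 44 names of short proteins in no list had a median of -0.23 (95% interval -0.36 to -0.0503), and 61 of long proteins 0.27 (0.16 to 0.34).

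Among single names in silica, copper-zinc superoxide dismutase, an antioxidant enzyme and a different name from the abundant one above, fell from 49.9 ± 19.5 to 15.6 ± 3.90 CPM (log2 fold change -1.69, SE 0.35, edgeR adjusted p = 0.0437). Tyrosine phosphatase domain-containing protein fell by 1.67, phosrestin i arrestin b arrestin/arp2_g2688 by 0.97, wd-repeat protein/arp2_g2370 by 0.98 and pre-mrna-splicing factor cwc22/arp2_g2533 by 0.86 on the log2 scale. Fibulin 1 and, named for an extracellular matrix protein, rose from 6.68 ± 2.71 to 16.8 ± 3.50 CPM (log2 fold change 1.32, SE 0.28, edgeR adjusted p = 0.0437). Disabled, calcium-activated chloride channel regulator 4/sw, denn domain-containing protein 4b and tgf-beta receptor type iii/sw rose by log2 fold changes of 0.61, 0.60, 0.57 and 0.55. Bromo adjacent domain-containing 1 protein, tumor necrosis factor alpha-induced protein 8 protein 3 and polyadenylate binding protein ii rose by 0.42, 0.42 and 0.39.

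In total 53 names passed in silica against control, 11 higher and 42 lower, and 1754 had an unadjusted p under 0.05. By camera with the preset correlation 9 lists passed. Lower than control were cytosolic ribosomal proteins (adjusted p = 1.80e-31), proteasome (2.25e-06), histones (0.00101; median -0.40), DNA replication and cell cycle (0.00399; median -0.25) and metal handling (0.0429; median -0.18). Higher were muscle (0.00800; median 0.41), neural transmission (0.00290; median 0.28), collagen and extracellular matrix (0.00290; median 0.32) and ecdysteroid and juvenoid signalling (0.0382; median 0.17). With an estimated correlation the adjusted p of these 9 lists lay between 0.587 and 0.624. No member of the 7 lists other than ribosomal proteins and proteasome passed over all names. Adjusted over the list alone, 7 histones fell and 1 rose, 4 metal handling names fell, and none passed in the other 5. Their members with the smallest p were histone h2b type 1-d (127 ± 4.85 against 169 ± 21.1 CPM), cyclin-d1-binding protein (11.4 ± 2.00 against 15.8 ± 2.67), metallothionein protein crs5 (101 ± 17.4 against 176 ± 58.8), myosin light chain kinase/arp2_g892 (1200 ± 255 against 531 ± 173), synaptic vesicle membrane protein vat-1 (30.9 ± 4.37 against 121 ± 80.9, against the direction of the neural list), laminin subunit alpha-3 (458 ± 32.1 against 331 ± 25.3) and nuclear hormone receptor hr96 (31.6 ± 1.80 against 25.3 ± 2.69). No silica library lay among the 5 at the negative end of the first principal component, and with that component as a covariate the medians of the DNA replication and cell cycle, muscle, and collagen and extracellular matrix lists were 0.0224, -0.0833 and -0.0579. The first 2 were then no longer past the threshold (adjusted p = 0.206 and 0.225), while the collagen list passed in the opposite direction (0.0292). That covariate also ended the calls of neural transmission (median 0.0232, adjusted p = 0.556), histones (-0.0964, 0.103) and ecdysteroid and juvenoid signalling (0.174, 0.0792). The adjusted p by the preset correlation was 0.0974 and 0.0601 for metal handling without control 4 and silica 4, and 0.0562 for ecdysteroid and juvenoid signalling without silica 4. The number of names called was 132 without control 1, 0 without each of control 2 to 5 and of silica 1, 4 and 5, and 9 and 5 without silica 2 and 3. It was 0 with the first principal component as a covariate or without the 5 libraries at its negative end, and 399 by DESeq2.

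Names called lower in each of the 3 exposures included ribosomal proteins. The falls called in silica included 27 of the 370 in nano_high and 14 of the 40 in nano_low, where the draws of unchanged groups gave 18.5 (95% range 2 to 37) and 6.28 (0 to 15). For these shared calls the one-sided permutation p was 0.184 and 0.0647. Ranked by limma's t as in the draws, lists of these sizes had 34 and 16 names in common. The one-sided permutation p was then 0.0498 and 0.0299, unadjusted, and 34 lies within its 95% range. The rises called in silica included 8 of the 391 in nano_high and 0 of the 7 in nano_low, where the draws gave 5.73 (0 to 11) and 0.955 (0 to 3), and by rank they were 9 and 0 (permutation p = 0.224 and 1). The 14 names called lower in all 3 exposures included 12 cytosolic ribosomal proteins, among them 60s ribosomal protein l23, 40s ribosomal protein s27 and 60s ribosomal protein l5/arp2_g6205, and the other 2 were atp synthase subunit s protein and immediate early response 3-interacting protein. The 3 comparisons share their controls, and no draws were made for names called in all 3. The mean log2 score of the ribosomal list per library was 0.287 ± 0.108 in control, -0.0789 ± 0.188 in nano_low, -0.0555 ± 0.124 in nano_high and -0.153 ± 0.189 in silica (n = 5 each). Two-sided exact permutation tests of these scores gave p = 0.0159, 0.0159 and 0.00794, the last the smallest that 5 against 5 libraries allow, and 0.206, 0.138 and 0.0516 after adjustment over 26 lists. For metal handling the score was 0.199 ± 0.117 in control, -0.101 ± 0.0437 in nano_low, -0.121 ± 0.104 in nano_high and 0.0222 ± 0.0707 in silica, with exact permutation p = 0.00794 in each comparison and 0.206, 0.138 and 0.0516 after adjustment. These score tests were chosen after the data had been seen. In all 3 comparisons even the smallest possible p stayed above 0.05 after adjustment, so the adjusted values do not decide for a list. Between nano_high and silica the fold changes against the shared controls had r = 0.498 and a covariance of 0.0743, and between nano_low and silica r = 0.80 and a covariance of 0.111. All 4 values lie within the simulated ranges for unchanged groups, -0.312 to 0.869 for r and -0.0192 to 0.115 for the covariance, and the mean r with split controls was 0.266 and 0.477.

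**Figure D4:**
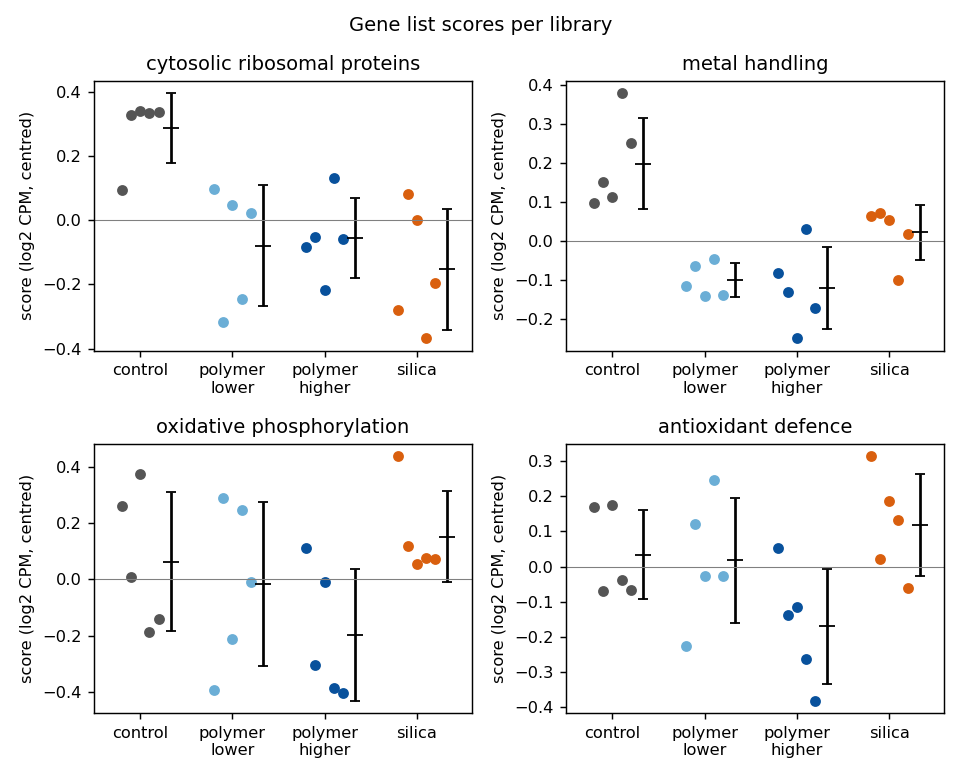
Mean centred log2 CPM per library (y axis) for the ribosomal, metal handling, oxidative phosphorylation and antioxidant lists, by group; points are libraries and bars the mean ± SD of 5 libraries. The ribosomal scores run from 0.0938 to 0.341 in control and reach at most 0.131 in nano_high.

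A direct comparison of the 2 polymer concentrations, the question of dose, found no name past the threshold. Of 84 oxidative phosphorylation names 77 lay lower in nano_high than in nano_low (median -0.22), and of 30 antioxidant defence names 26 did (median -0.20). The 44 names of short proteins in no list had a median of -0.0789 (95% interval -0.15 to -0.0230). The members with the smallest p were cytochrome c oxidase subunit, part of the last respiratory complex (2601 ± 243 against 3408 ± 573 CPM, edgeR adjusted p = 0.644), and gh25379p, secretable thioredoxin peroxidase, thioredoxin peroxidase 2, thioredoxin peroxidase (80.7 ± 6.86 against 93.8 ± 8.19 CPM, edgeR adjusted p = 0.644). The names with the smallest p, given as not past the threshold, were cyclin-t2 (74.8 ± 7.86 against 58.5 ± 1.5 CPM), la-related protein (33.4 ± 4.77 against 24.5 ± 1.80) and plasminogen activator inhibitor 1 rna-binding protein/arp2_g6385 (469 ± 54.0 against 324 ± 65.6) on the higher side. On the lower side they were integral membrane efflux protein efpa (34.9 ± 11.0 against 60.2 ± 6.20), tumor necrosis factor alpha-induced protein 8 protein 3 (18.3 ± 1.10 against 24.4 ± 2.44) and phospholipase a1 member a (2.45 ± 0.758 against 4.75 ± 0.241). edgeR called 0 of 7564 names, with a smallest adjusted p of 0.521 and 511 names at an unadjusted p under 0.05, and DESeq2 called 4. By camera with the preset correlation the 2 lists passed (adjusted p = 1.26e-09 and 1.94e-05), and with an estimated correlation their adjusted p were 0.917 and 0.739. The counts against control, 761 and 47, do not test the difference between the concentrations, which this comparison does.

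Set against silica at the same stated concentration, names called lower in nano_high included mitochondrial and antioxidant transcripts. As lists, oxidative phosphorylation and antioxidant defence did not pass camera with an estimated correlation (adjusted p = 0.707 each). By fry the adjusted p were 0.107 and 0.0158. Of 84 oxidative phosphorylation names 11 fell and 1 rose, and 25 fell and 2 rose adjusted over the list alone (median -0.39). Against control the list's median was -0.23 in nano_high and 0.15 in silica. In silica 64 of the names lay above control, and the list did not pass camera with the preset correlation (adjusted p = 0.0642). The gap is thus not a fall in nano_high alone. Nadh dehydrogenase [ubiquinone] 1 subunit c2 was at 6.82 ± 2.07 against 14.9 ± 3.44 CPM in silica (log2 fold change -1.13, SE 0.20, edgeR adjusted p = 0.00787), nadh-ubiquinone oxidoreductase chain 4l at 46.3 ± 17.8 against 156 ± 37.4, and nadh-ubiquinone oxidoreductase chain at 1066 ± 164 against 2196 ± 338. Nadh dehydrogenase [ubiquinone] iron-sulfur protein 4, mitochondrial was lower by a log2 fold change of -0.72, stomatin protein 2, mitochondrial by -1.57 and atpase inhibitor mai-2, mitochondrial by -1.41. Of 30 antioxidant defence names 7 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone (median -0.34), with thioredoxin-2 at 125 ± 26.9 against 210 ± 24.0 CPM and glutaredoxin-related protein 5, mitochondrial at 7.46 ± 2.22 against 14.4 ± 2.18. The 44 names of short proteins in no list had a median of -0.0647 (95% interval -0.26 to 0.0949). The one that rose was copper-zinc superoxide dismutase, at 43.6 ± 24.9 against 15.6 ± 3.90 CPM. Of 82 fatty acid and lipid metabolism names 2 fell and 1 rose, and 1 fell and 1 rose adjusted over the list alone (median -0.16); carnitine o-acetyltransferase and 3-hydroxyacyl-coa dehydrogenase type ii/arp2_g924 fell by 0.31 and 0.53 and fatty acid-binding protein rose by 0.62 on the log2 scale.

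Higher in nano_high than in silica were 3 cytosolic ribosomal proteins, 60s ribosomal protein l13 (1790 ± 234 against 1350 ± 93.4 CPM), 60s ribosomal protein l7 and 40s ribosomal protein s4/arp2_g5907, and the count was 3 adjusted over the list alone (median 0.11). Of 18 histone names 2 rose, histone h1.0/sw (160 ± 42.6 against 91.1 ± 7.00 CPM) and histone h3 type/arp2_g42, and of 49 DNA replication and cell cycle names 2 rose, g1/s-specific cyclin-e1 (43.3 ± 33.3 against 15.9 ± 3.72 CPM) and g1/s-specific cyclin-d2, which drive entry into DNA synthesis; both counts were 2 adjusted over the list alone. Of 19 muscle names 1 fell, calcium-binding protein, cex ca2+-sensing low molecular weight gtpase, rh52364p, sarcoplasmic calcium-binding protein (18.1 ± 4.91 against 33.0 ± 9.79 CPM), and 2 fell adjusted over the list alone. Notch/arp2_g5857, a cell fate receptor, rose from 3.42 ± 1.20 to 11.5 ± 2.97 CPM (log2 fold change 1.75, SE 0.28, edgeR adjusted p = 0.00459). Transcription factor atf1, zinc finger, histone-lysine n-methyltransferase setd2 and glutathione s-transferase c-terminal domain-containing protein rose by 3.59, 2.42, 2.37 and 1.45. The first 3 ranged widely in nano_high (22.9 ± 34.2, 3.65 ± 3.78 and 890 ± 884 CPM), and without nano_high 4 their log2 fold changes were 2.08, 1.63 and 1.59, no longer called (adjusted p = 0.138, 0.130 and 0.139). In control, setd2 stood at 1008 ± 627 CPM. Conserved protein/arp2_g5262 was at 40.8 ± 3.49 against 0.132 ± 0.295 CPM, and expressed protein/arp2_g1170 at 190 ± 363 against 2.43 ± 1.29. The former was no longer called without silica 1 or 3 (adjusted p = 0.0864 and 0.0505), nor were the latter and cyclin-e1 without nano_high 5 (0.187 and 0.127, with log2 fold changes of 3.71 and 0.86). Transcription factor atf1 and expressed protein/arp2_g1170 also had strong negative loadings on the first principal component (-0.0461 and -0.0616). Nano_high 4 and 5, and no silica library, lay at that end. Vacuolar protein sorting-associated protein vps13d/arp2_g6355 and conserved protein/arp2_g1399 were at 0 in nano_high and at 0.873 ± 1.55 and 0.890 ± 1.10 CPM in silica. They were thus at least 81.6-fold and 83.2-fold lower against 3 counts over the group, or 17.1-fold without silica 3 and 38.1-fold without silica 2. Vacuolar atpase assembly integral membrane protein vma21, peptidyl-prolyl cis-trans isomerase fkbp14, eno/arp2_g1214 and serine/threonine-protein phosphatase 4 catalytic subunit had log2 fold changes of -3.59, -2.33, -2.23 and -1.59. Of the gut lining proteins in the list of 24 peritrophic matrix and mucin names, cdd: cbm_14, chitin binding peritrophin-a domain rose by 1.35 and mucin 55b by 0.81, and mucin-17 fell from 6587 ± 1219 to 3087 ± 390 CPM. Of 37 innate immunity names 3 fell, gram-negative binding protein gnbp (log2 fold change -0.80), galectin-2 (-0.30) and ubiquitin thioesterase otu1 (-0.24), an enzyme outside immunity that matches by its name.

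In total 405 names passed in nano_high against silica, 179 higher and 226 lower. More were higher than lower with median-ratio scaling (218 and 203), with no filter on low values (221 and 199), by DESeq2 (512 and 407), and without nano_high 1 (370 and 278), 3 (353 and 261) or 4 (77 and 71). By camera with the preset correlation 7 lists passed: oxidative phosphorylation (adjusted p = 9.16e-12), antioxidant defence (3.76e-05), DNA replication and cell cycle (0.00238; median 0.21), histones (0.0379; median 0.34), fatty acid and lipid metabolism (0.0379), muscle (0.0379; median -0.22) and cytosolic ribosomal proteins (0.0471). With an estimated correlation their adjusted p lay between 0.707 and 0.905. Nano_high 4 and 5 and no silica library lay at the negative end of the first principal component, and with that component as a covariate the medians of the ribosomal and muscle lists were -0.0390 and 0.0827. Single libraries ended 5 of the list calls by the preset correlation. The adjusted p of the ribosomal list reached 0.387 without nano_high 4, that of histones and of DNA replication and cell cycle 0.129 and 0.125 without nano_high 5, and that of muscle and of fatty acid and lipid metabolism 0.135 and 0.105 without silica 1. All 5 also ended with the component as covariate, and histones (0.0591) with names that match by wording alone taken out. The number of names called was 112, 614, 148 and 77 without nano_high 2, 3, 4 and 5, 648 without nano_high 1, and 90, 115 and 180 without silica 1, 4 and 5. It was 38 without the 5 libraries at that end, 36 when only the 2 groups entered the fit and 919 by DESeq2.

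**Figure D5:**
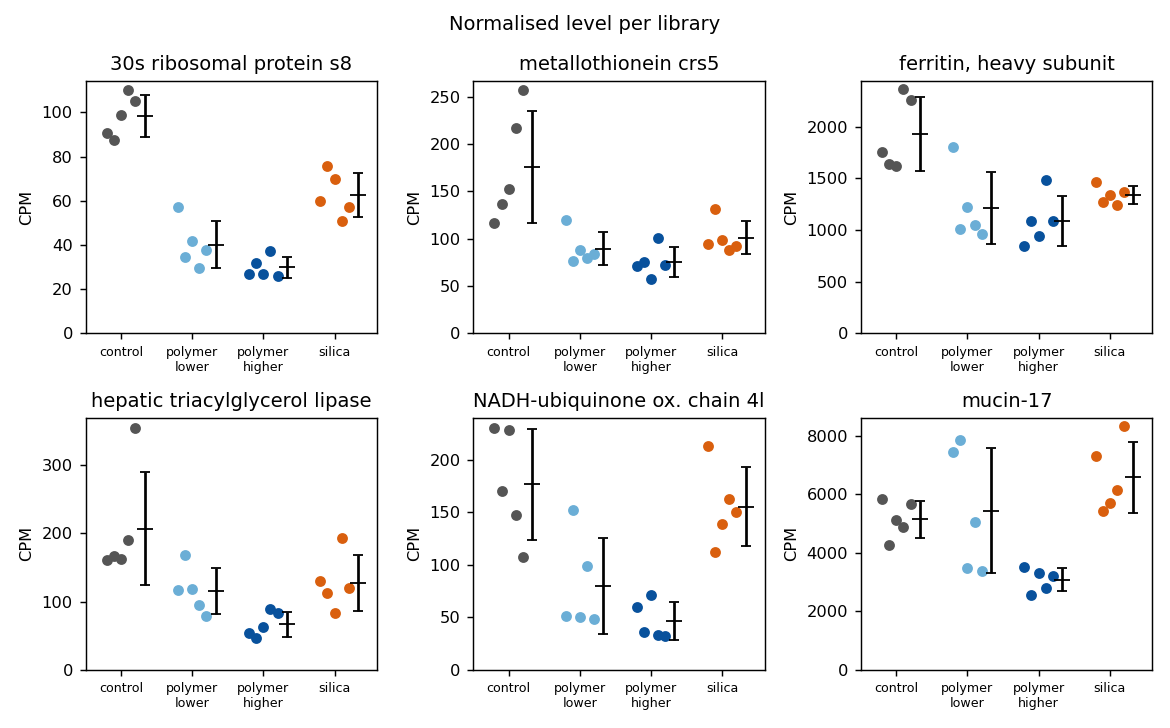
CPM per library (y axis, from 0) of 6 named transcripts by group; points are libraries and bars the mean ± SD of 5 libraries. The first panel, 30s ribosomal protein s8/arp2_g2243, has means of 98.5 CPM in control, 40.1 in nano_low, 29.7 in nano_high and 62.6 in silica.

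The remaining 13 of the 26 lists did not pass in any of the 5 comparisons by camera with the preset correlation. The lowest adjusted p was 0.145 for 6 hemoglobin names, 0.0782 for 42 cuticle proteins, 0.139 for 26 chitin turnover names, 0.0642 for 24 peritrophic matrix and mucin names and 0.100 for 22 digestive proteases. It was 0.133 for 68 digestive carbohydrases and lipases, 0.0503 for 28 cytochrome P450 names, 0.0750 for 33 phase II conjugation names, 0.399 for 17 ABC transporters and 0.399 for 47 heat shock and chaperone names. It was 0.125 for 37 innate immunity names, 0.530 for 15 glycolysis names and 0.0782 for 19 germline and oogenesis names. The 1 hemoglobin-list name called in nano_high was alpha-globin transcription factor cp2, a regulator and not a globin.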

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

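The tests of a single control library, of short transcripts and of the epidermis and moult cycle were chosen only after the result was seen. In 32 of 317 groups of 5 values, 1 library lay so far from the other 4 that its gap exceeded 0.71 of the group's range, where chance gives about 1 in 20. In control, control 1 had a ribosomal list score of 0.0938 against 0.329 to 0.341 in the other 4 libraries. Homeobox protein abdominal-a stood at 1.22 CPM in control 4, mitogen-activated protein kinase kinase kinase 19 at 11.0 CPM in control 2, hepatic triacylglycerol lipase at 354 CPM in control 5, and in control 3 thioredoxin, mitochondrial at 94.4 CPM and nuclear receptor corepressor at 82.2 CPM.

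In nano_low, nano_low 1 had 120 CPM of metallothionein protein crs5 (76.1 to 87.7 in the others) and 341 CPM of 40s ribosomal protein s16. Nano_low 5 had 98.9 CPM of casc3, 61.1 CPM of cyclin-t2, 437 CPM of plasminogen activator inhibitor 1 rna-binding protein/arp2_g6385 and 4.33 CPM of phospholipase a1 member a, and nano_low 3 had 21.4 CPM of la-related protein. In nano_high, nano_high 1 had 5.67 CPM of sterol regulatory element-binding protein/arp2_g3160 and 3666 CPM of peptidyl-prolyl cis-trans isomerase fkbp14 (1070 to 1433 in the others). Nano_high 4 had 0.0232 CPM of potassium/chloride symporter/arp2_g622, 49.1 CPM of group xv phospholipase a2, 612 CPM of pancreatic triacylglycerol lipase and 82.6 CPM of transcription factor atf1, and nano_high 3 had 0.0523 CPM of ubiquinol-cytochrome c reductase iron-sulfur subunit/arp2_g2003. Nano_high 5 had 101 CPM of g1/s-specific cyclin-e1, 835 CPM of expressed protein/arp2_g1170 (1.28 to 102 in the others) and 17.4 on the second principal component.

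In silica, silica 1 had a total of 54.86 in units of 1000000 counts (7.91 to 18.22 in the others) and 98.1 CPM of phosrestin i arrestin b arrestin/arp2_g2688, and silica 5 had 50.4 on the second principal component and 3.34 CPM of atpase inhibitor mai-2, mitochondrial. Silica 2 had 131 CPM of metallothionein protein crs5 and 2.82 CPM of conserved protein/arp2_g1399. Silica 3 had 3.63 CPM of vacuolar protein sorting-associated protein vps13d/arp2_g6355 and 0.660 CPM of conserved protein/arp2_g5262. Silica 4 had 16.2 CPM of 26s proteasome non-atpase regulatory subunit/arp2_g1763.

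Cytosolic ribosomal proteins were lower than control in all 3 exposed groups, with medians of -0.39, -0.38 and -0.45. With each control library left out in turn the highest of the 3 medians was -0.34, which argues against a single control library, and with the first principal component as a covariate it was -0.28, which argues against that component as the whole cause. A loss of short transcripts would lower other short proteins as far. The medians of these were -0.13 (95% interval -0.22 to -0.0471) in nano_low, -0.25 (-0.36 to -0.19) in nano_high and -0.0425 (-0.14 to 0.0820) in silica. By these intervals the short names fell less than the ribosomal ones in nano_low and silica, while the intervals overlapped in nano_high. The intervals resample names, which vary together, and leave out the spread between libraries, so they do not decide the question. Of these 79 short names 35 are in the oxidative phosphorylation or antioxidant list, the other 44 had medians of -0.15 (-0.30 to -0.0591), -0.26 (-0.41 to -0.11) and -0.23 (-0.36 to -0.0503), and long proteins 0.22 (0.13 to 0.29), 0.37 (0.28 to 0.43) and 0.29 (0.19 to 0.37), so a part related to length stays open in all 3 groups. All 3 comparisons use the same controls, so a control group that was high as a whole stays open too. A difference between sequencing pools and an effect of the exposures also stay open, untested.

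More names were called against control in nano_high (761) than in nano_low (47). With every library thinned to the smallest total, the ratio of the counts was at least 14.98 over 5 draws, which argues against the lower counting error of the deeper nano_high libraries. Thinning cannot remove a difference between sequencing pools, which stays open, untested. Without nano_low 1 the nano_low count was 236, so how far that library lowers the count cannot be told apart from the concentration, since 1 library of 5 decides it. The concentration itself stays open, and the direct comparison called 0 names by edgeR (511 at an unadjusted p under 0.05, 4 by DESeq2).

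Libraries of 3 groups spread along the first principal component. Thinning left the component in place (correlation 0.9997 between the scores before and after), which argues against depth; its Pearson r with log10 total was -0.0372 and its Spearman rho 0.116 (permutation p = 0.874 and 0.629), and r was 0.239 without the 2 farthest libraries. A smaller share of epidermis would lower all cuticle names together, but 6 lay among the 100 strongest loadings at the end opposite to the other 19, against 0.555 by chance (exact hypergeometric p = 1.64e-05). That p treats names as independent draws, although cuticle names vary together, so it overstates the evidence. Cuticle names at both ends, at least 6 at either, would go with animals at different points of the moult cycle. That hypothesis was found and tested on the same data. Neither explanation was set against the yolk and germline scores, which also followed the component (r = -0.887 and -0.861).

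For the counts of called names, 100 of the 126 splits of each comparison's 10 libraries were drawn. Counting the real split itself, as many names were called in 4 splits for nano_low against control (47, highest other 1403), 3 for nano_high against control (761, highest other 1926), 1 for silica against control (53, highest other 1) and 1 for nano_high against silica (405, highest other 1). In the 2 comparisons with silica no other split drawn came near the real count. The silica count against control fell to 0 without any 1 of several libraries, however, which the splits do not address. For nano_low and nano_high against control other splits called far more names, and these shares are not adjusted over the comparisons. Chance therefore cannot be excluded there. For nano_high against nano_low the real count was 0, which any split reaches (highest other 1886), so the splits decide nothing there. The splits with many calls point to a structure of the samples: that with 1403 put nano_low 1 and control 4 and 5 on one side, together with nano_low 3 and control 2, and that with 1926 put nano_high 4 and 5 and control 4 and 5 on one side, together with control 2. The libraries at the negative end of the first principal component thus lay on one side in both. For lists past the threshold with the preset correlation, 80, 69, 32, 94 and 49 of the 100 splits gave as many as the real 4, 6, 9, 2 and 7 (highest others 17, 12, 13, 17 and 16), so chance cannot be excluded for the number of lists.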

How the results depend on the processing

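The settings called thinning, first principal component, limma with a pseudocount of 1, lists without false matches, the 3 most abundant names left out, and the fits without 5 libraries were chosen after seeing the data. For nano_low against control the count of 47 became 227 by DESeq2, 187 with the first principal component as covariate, 86 and 88 with limma on log2(CPM + 1) and log2(CPM + 5), 167 with sample weights, 30 with quantile normalization, 3 with only the 2 groups, and 15 thinned to the smallest library (15 to 40 over 5 draws). Leaving out 1 library gave 8 to 236. For nano_high against control the count of 761 became 1152 by DESeq2, 1748 with the component and 372 with only the 2 groups, and 413 to 967 with 1 library left out. For silica against control the count of 53 became 399 by DESeq2, 555 with sample weights, 401 with only the 2 groups, 21 thinned (21 to 88 over 5 draws), 1 with the variance trend off, and 0 with the component, with quantile normalization or without the 5 libraries at one end of the component. Leaving out 1 library gave 0 to 132. For nano_high against nano_low the count of 0 became 4 by DESeq2 and stayed 0 with each library left out. For nano_high against silica the count of 405 became 919 by DESeq2, 652 with the component, 1162 with sample weights, 36 with only the 2 groups, 263 thinned and 38 without the 5 libraries, and 77 to 648 with 1 library left out. Names whose groups did not overlap numbered 196, 657 and 89 in nano_low against control, silica against control and nano_high against nano_low, where chance gives 0.794% or 60.03 names. No scaling moved the share of lower calls by over 10 percentage points. The cause of these shifts was not tested.

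The replicate number as a block changed the counts to 13 for nano_low, 0 for silica and 267 for nano_high against silica, and left the other counts within 1.5 times. Replicate numbers do not pair the samples: of 30 same-numbered pairs, 8 had a correlation of deviations over 0.1 (range -0.636 to 0.650), and 3 of 20 libraries correlated best with their own number. The 28 list results past the threshold became 0 with an estimated correlation and 25 to 46 with 1 library left out. Of 504 values of these lists 6 reversed: with the first principal component as covariate, silica against control gave 0.0224 for DNA replication and cell cycle, -0.0833 for muscle and -0.0579 for collagen and extracellular matrix, and nano_high against silica -0.0390 for cytosolic ribosomal proteins and 0.0827 for muscle, and without the 5 libraries histones gave -0.00603 there. Of 1836 values of list results not past the threshold, which are left out of that count, 179 changed sign. The ribosomal medians against control were -0.39, -0.37 and -0.46 with median-ratio scaling. The correlation of the polymer fold changes became 0.353 with the controls split, and 0.584 to 0.828 with 1 library left out. Of 4519 values of named genes 0 reversed, and those called under all settings numbered 2 of 19, 33 of 66, 0 of 21 and 1 of 41 in the comparisons with calls. Depth limits names of low abundance most in silica 5, at 7912434 counts.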

Other observations

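Vitellogenin, the yolk precursor made by egg-producing females, was among the most abundant names. The score of the yolk names followed the first principal component (r = -0.887 over 20 libraries). Vitellogenin-1 precursor stood at 47220 ± 20045 CPM in control, 35665 ± 18012 in nano_low, 58777 ± 48016 in nano_high and 19409 ± 7328 in silica (n = 5 each), and edgeR's adjusted p were 0.715, 0.743 and 0.154 against control and 0.0618 for nano_high against silica. The main hemoglobin name, di-domain hemoglobin precursor, stood at 3541 ± 464 CPM in control, 3589 ± 801 in nano_low, 3746 ± 1474 in nano_high and 3045 ± 371 in silica, with adjusted p of 0.971, 0.872 and 0.546 against control. The abundant copper-zinc cu-zn superoxide dismutase. stood at 96220 ± 51825 CPM in control, 145443 ± 55166 in nano_low, 152746 ± 23274 in nano_high and 171847 ± 24000 in silica (edgeR adjusted p = 0.427, 0.213 and 0.157 against control).

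Words in the names gave 171 further sets, chosen after the data had been seen. Of 20 names with the word pore, most of them nuclear pore proteins and some ion channels, 9 were higher in nano_high than in silica and 0 lower, and of 419 with mitochondrial 2 were higher and 39 lower. Of 47 with homeobox, transcription factors of body patterning, 3 were higher in nano_high than in control and 0 lower, where 391 of all 7564 names were higher, a similar share. Of 145 with transcription 17 were higher and 1 lower. With the preset correlation the adjusted p were 1.52e-06, 1.30e-13, 0.000843 and 0.00155, and with an estimated correlation 0.628, 0.628, 0.461 and 0.466. Names of long proteins had median log2 fold changes of 0.22 (95% interval 0.13 to 0.29) in nano_low, 0.37 (0.28 to 0.43) in nano_high and 0.29 (0.19 to 0.37) in silica against control. Conserved protein/arp2_g5262 was above 20 CPM in 5 of 5 nano_high, 3 of 5 nano_low, 1 of 5 control and 0 of 5 silica libraries.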
